A study of Homo sapiens with 20 samples.

How the data were processed

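The values are array intensity values, deposited on a linear scale and never below a floor of 20; the submitters' processing notes name MAS5 version 5, and per the series' design text differences in intensity between arrays were normalised with dChip. Which of these tools made the deposited values is not given in the sources used here. The samples are 20 arrays, all of vehicle cultures, in 10 lines with 2 duplicates each, and the class of each line comes from the series' design text. RNA was extracted with a column kit, per the labels' protocols, apart from CUTLL1 replicate 1, whose labels conflict: the title and treatment field give vehicle, the source name gives the inhibitor, and another reagent is listed for extraction. It was kept as vehicle, and left out as an alternative.

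Each value was turned into log2(intensity + 16), so differences of low genes are understated. Of 54675 probe sets on the array, 41097 have 1 gene symbol in the platform annotation used, 1801 have several and 11777 are unnamed here; probe sets with several symbols or none were not named. Symbols were updated through their gene identifiers with the RefSeq table of assembly GRCh38.p14, which matched 41043 of the 41097, and no coordinates are given. For each gene the probe set with the highest mean over the 20 arrays was used, and genes were kept when that mean was at or above the 40th percentile of all probe sets, which left 14468 genes of 19775.

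Response is a property of a line, so the line was the replicate. The mean of its 2 arrays entered limma 3.58.1 (R 4.3.3), lmFit and eBayes with trend, comparing 5 resistant with 5 sensitive lines, with Benjamini-Hochberg adjustment at 0.05. The number of lines, 5 per class, limits the precision. The 29 gene lists were tested with camera at a preset correlation of 0.01. The panel was tested two-sided with an exact permutation test over all 252 assignments. Differences among lines were tested with limma's F-test on 20 arrays, and a gene singled out a line when its contrast with the mean of the other 9 passed and its level lay at least 2 log2 units beyond the nearest other line. Duplicates are separate cultures of a line, so p-values among lines measure only the spread between cultures of that line.

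Genes were named by a rule fixed before the data were examined: per direction, up to 10 genes past the threshold with no overlap of line means and the largest difference, then up to 5 by smallest p where fewer passed; from each list up to 3 members with the smallest p; among lines, detected members of the oncogene, thymocyte-stage and CDKN2A-locus lists, and per line up to 3 genes singled out upwards and 1 downwards. Genes of receptor variable segments and sex-linked markers were not ranked. Some preset genes are not reported here.

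The procedures were tested on simulated data drawn from the real means and spreads of the 14468 genes. For the comparison of resistant with sensitive lines, 100 genes changed by 1 log2 unit were recovered in 34% of cases and 100 changed by 2 units in 92%, with 5 unchanged genes called, and 0 genes were called when none changed. Genes raised by 4 log2 units in 1 line were recovered in 100% of cases by the F-test and by the single-line rule. In that run the lines were otherwise given the same level and only duplicates varied. It therefore does not show recovery among lines that differ, as the real ones do. A list lowered by 1 log2 unit was the only list called in its simulation. With no difference, 4.7% of exact tests gave p at or under 0.05. The simulated genes were independent, so this says nothing about lists whose members move together.

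Alternatives covered the scaling between arrays, the pseudocount, the filter, the choice of probe set, the treatment of duplicates, the moderation of variances, the list test and each line left out. The clusters of arrays came from average-linkage clustering of 208 probe sets of gene families not used by lymphoblasts; the fits that use these clusters, those leaving out each single array, and the comparison of array quality measures between classes were chosen after the data had been seen.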

Results

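Transcript levels were measured on 20 oligonucleotide arrays covering the human genome, each hybridised with RNA from a culture of a T-cell acute lymphoblastic leukaemia (T-ALL) cell line kept for 24 h in vehicle (DMSO). The 10 established lines fall into 2 classes by their response to gamma-secretase inhibitors (GSI), drugs that block the cleavage that activates NOTCH receptors. The 5 GSI-resistant lines are RPMI8402, PF382, MOLT3, CCRF-CEM and P12-ICHIKAWA, and the 5 GSI-sensitive lines are KOPTK1, HPB-ALL, ALL-SIL, DND41 and CUTLL1. Each line has 2 duplicate cultures. Cultures given the inhibitor are not analysed here, so every comparison concerns the state of the lines without it. Median intensity per array ran from 64.4 to 83.4, and between 11.2% and 22.1% of probe sets sat at the lowest deposited value of 20, called the floor below. Duplicates correlated at 0.977 to 0.991 across probe sets, and for all 20 arrays the duplicate was the closest match, against at most 0.947 with any array of another line.

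The first comparison asked which genes differ between resistant and sensitive lines. ALDH1A2, which makes retinoic acid from retinaldehyde, had the widest difference: 10.61 ± 0.80 (SD, n = 5) log2 units in resistant lines against 5.84 ± 1.50 (SD, n = 5) in sensitive ones. It was at the floor in 4 sensitive lines and read 8.52 in HPB-ALL, so the difference of 4.77 ± 0.65 (SE) corresponds to at least 27.2-fold on this scale. SPRY1, an antagonist of receptor tyrosine kinase signalling, and CD47, the surface protein that inhibits phagocytosis through SIRPA, were also higher in resistant lines, by 1.72 ± 0.26 and 0.95 ± 0.15 log2 units (SE). PHTF1 and CACNG3, the latter a subunit that regulates AMPA-type glutamate receptors, were lower, with differences of -1.25 ± 0.19 and -1.79 ± 0.27 log2 units (SE).

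In total 13 of 14468 genes passed an adjusted p of 0.05 in limma on the 10 line means, 10 higher and 3 lower in resistant lines, and all 13 shared the same adjusted p of 0.0429. This balance was not stable: it was 0 higher and 4 lower with no filter and 22 and 39 without RPMI8402, but 10 and 4 with quantile normalisation. Besides those above, the neuronal antigen PNMA2 was higher by 3.04, the transcription factor ONECUT2 by 2.80, the vesicle protein SYNGR1 by 2.61, the F-box protein FBXL16 by 2.59, the ubiquitin ligase MIB2 by 1.75, the actin-binding CNN2 by 1.38 and the BBSome subunit BBS7 by 1.08 log2 units. ONECUT2 was at the floor in 4 sensitive lines, PNMA2 and SYNGR1 in 2 each and SPRY1 in 1, and CACNG3 was there in 3 resistant lines and PHTF1 in 1. The third lower gene was PPIA, cyclophilin A, with a difference of -0.50 ± 0.07 (SE). The probe sets of PPIA and CNN2 are of a type that can bind several transcripts, and PPIA has many processed copies. Neither gene has another detected probe set with only 1 gene symbol, so these values are uncertain. Of other detected probe sets, all 6 of CD47 (1.02 to 2.38) and the single one of ALDH1A2 (2.90) had the same sign. Those of other genes differed by less: 0.04 each for PNMA2 and SYNGR1, 0.45 and 0.49 for ONECUT2, 0.08 and 0.56 for MIB2, and 0.45 for BBS7. Leaving out any 1 resistant line put another probe set of ONECUT2 in use, with differences of 0.41 to 0.60, and leaving out P12-ICHIKAWA did so for SYNGR1 (0.09); with the probe set held fixed, leaving out each line gave 2.51 to 3.11 for ONECUT2 and 2.42 to 2.93 for SYNGR1. Below the threshold, the 5 lower genes with the smallest p were LINC01896 (-1.15), the B-lineage factor EBF1 (-1.69), IGSF11 (-2.18), the heterochromatin protein CBX3 (-0.75) and TM4SF1 (-1.32), with limma adjusted p between 0.0522 and 0.0616; the 3 other probe sets of CBX3 gave -0.55 to -0.10. The ratio of 3' to 5' signal, a measure of RNA quality, was for GAPDH 0.980 ± 0.011 (SD, n = 5) in resistant and 0.932 ± 0.028 in sensitive lines (exact permutation p = 0.0159, adjusted p = 0.0794 over 5 array measures). For ACTB it was 1.258 ± 0.118 against 1.124 ± 0.079 (exact p = 0.0714).

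**Figure D1:**
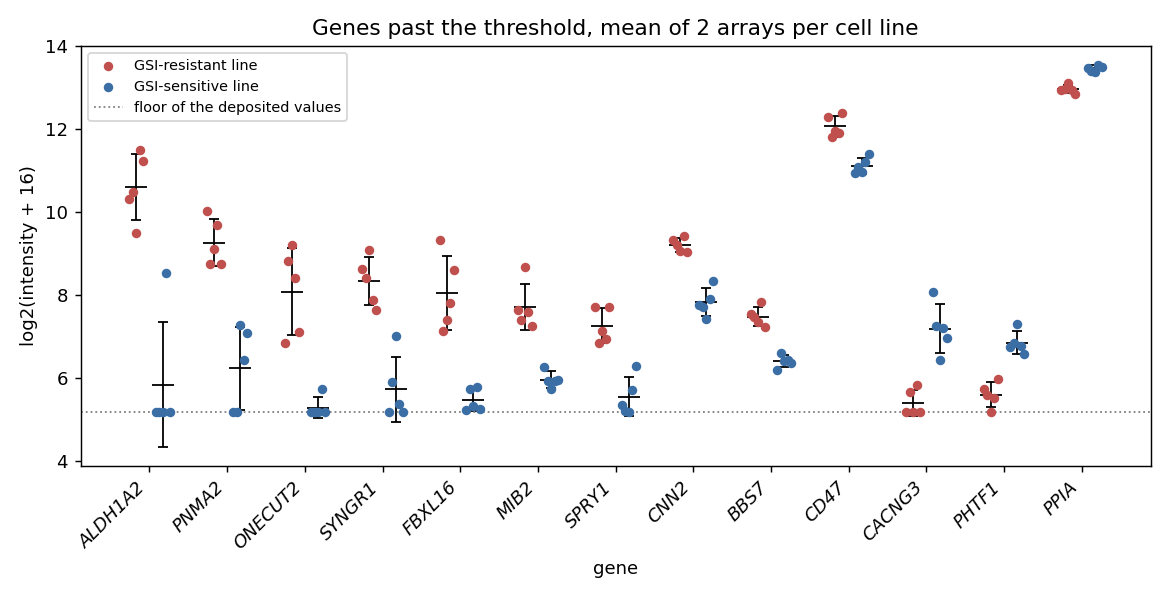
Levels of the 13 genes past the threshold, as log2(intensity + 16), with 1 point per cell line (mean of 2 arrays), the horizontal mark the mean and the bar the SD of 5 lines. ALDH1A2 lies at 9.49 or above in the resistant lines and at the floor, the dotted line, in 4 of the 5 sensitive lines.

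The threshold was only just crossed, and the count fell to 0 without CUTLL1 replicate 1, with array medians set equal, and when either ALL-SIL or CUTLL1 was left out. MOLT3, P12-ICHIKAWA and PF382, all resistant, stood apart on probe sets of olfactory receptor, keratin-associated, taste receptor and defensin genes, and ALL-SIL, HPB-ALL and KOPTK1, all sensitive, formed a further block. Without the first 3 lines, 2 resistant against 5 sensitive lines gave 7 genes. With the cluster as a fixed term 9 genes passed, 4 of them (FBXL16, SPRY1, CD47 and PPIA) among the 13. Because the first 3 lines are all resistant, that term leaves the same 2 against 5 lines, with the same differences. Of the other 9 of the 13, 8 kept a difference within 1.5 times and had a larger SE, such as ALDH1A2 at 4.93 ± 0.92 against 4.77 ± 0.65, while ONECUT2 was at 1.69 ± 0.24 against 2.80 ± 0.42 (SE). With both blocks as terms, which leaves CCRF-CEM and RPMI8402 against CUTLL1 and DND41, 4 genes passed. All 13 kept their sign without MOLT3, P12-ICHIKAWA and PF382, which was fixed in advance because their line means do not overlap between classes. No value within either block can be had because each holds 1 class. The line means did not overlap between classes for 472 genes, 174 higher and 298 lower in resistant lines. Chance gives 0.794% of genes on average, or 115. The count for other splits of the lines was not computed, so whether 472 lies beyond chance is not known. The blocks of arrays, each within 1 class, may also add to it.

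**Figure D2:**
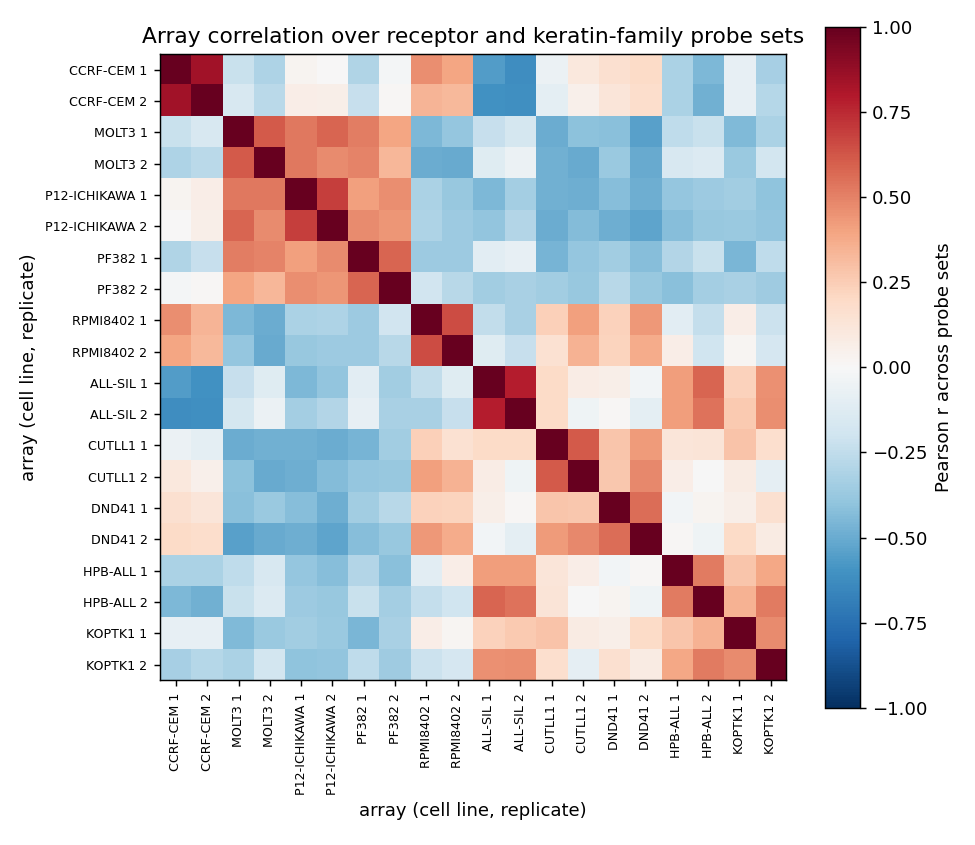
Pearson correlation between the 20 arrays over 208 probe sets of olfactory receptor, keratin-associated, taste receptor and defensin genes, after subtracting each probe set's mean; both axes list arrays by cell line and replicate. The arrays of MOLT3, P12-ICHIKAWA and PF382 form a block with a mean correlation between lines of 0.47, and those of ALL-SIL, HPB-ALL and KOPTK1, all sensitive, another with 0.41.

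Single genes of the NOTCH pathway and of T-ALL biology were compared in a preset panel. DTX1, a NOTCH1 target, read 8.55 ± 1.08 (SD, n = 5) in resistant and 10.47 ± 0.52 (SD, n = 5) in sensitive lines, without overlap, and its exact permutation p of 0.00794 is the smallest that 252 assignments can give. CDKN2A differed by -3.50 (exact p = 0.0317; -1.57 on its other detected probe set, exact p = 0.0159), MYC by -1.19 (exact p = 0.0556) and PIK3R1, a regulatory subunit of PI3K, by -0.57 (exact p = 0.0238; -0.32 and -0.28 on the others). TAL1 differed by 1.94 (exact p = 0.0397), but its other detected probe sets gave -0.76 (exact p = 0.0238) and 1.10 (exact p = 0.0635), so its direction depends on the probe set. After Benjamini-Hochberg adjustment over the 18 panel genes none of these passed, the lowest adjusted exact p being 0.143 for DTX1. A single gene alone can reach no lower with these lines, so the panel test could hardly pass a gene. In limma over all genes 0 of them passed, too. NOTCH1 itself read 10.28 ± 0.46 against 10.77 ± 0.97 (SD, n = 5 each; exact permutation p = 0.325), NOTCH3 8.98 ± 2.34 against 9.96 ± 1.21 (exact p = 0.492), and HES1 9.66 ± 0.89 against 8.91 ± 1.80 (exact p = 0.444). The other HES1 probe sets differed by 0.50 and -0.53, so its direction, too, depends on the probe set.

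Gene lists fixed in advance were compared next. Over all genes tested the median difference was -0.06 log2 units, and -0.02 without MOLT3, P12-ICHIKAWA and PF382, so list medians are to be read against these values. Genes of cholesterol and fatty acid synthesis were lower in resistant lines: 17 of 20 members had a negative difference and the median was -0.43 log2 units (camera adjusted p = 0.00253, but adjusted p = 0.821 with an estimated correlation). HMGCS1, which makes the mevalonate precursor, differed by -1.34 ± 0.26 (SE), MVD by -0.76 ± 0.20 and the sterol carrier STARD4 by -0.77 ± 0.20; 5 members passed when adjusted over the list alone and 0 over all genes. This list was the only one of 29 past the threshold, and its call is weak: 0 lists passed with an estimated correlation or in fry's directional test, and 94 of 100 splits of the lines into 5 and 5 gave at least 1 list. In fry's mixed test, which asks for change in either direction, 7 lists passed, this one among them (adjusted p = 0.00495). The median was -0.64 without MOLT3, P12-ICHIKAWA and PF382.

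**Figure D3:**
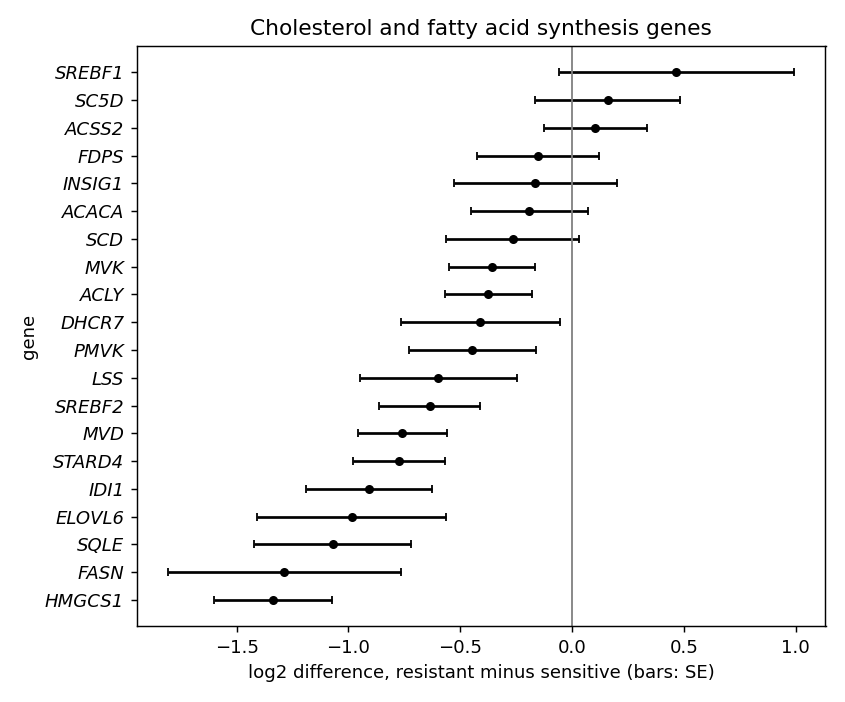
Difference between resistant and sensitive lines for the 20 genes of cholesterol and fatty acid synthesis, in log2 units, with bars of 1 SE from limma. Points left of 0 are lower in resistant lines; 17 of the 20 lie there.

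Other lists did not pass. Cell cycle and DNA replication genes had a median of -0.26, with 25 of 36 members lower (camera adjusted p = 0.0714); the helicase subunits MCM5 (-1.01 ± 0.23, SE) and MCM6 (-0.71 ± 0.17) and thymidylate synthase TYMS (-0.48 ± 0.12) were among 4 that passed when adjusted over the list alone, but the other detected probe set of MCM6 (0.29) and 1 of the 2 of TYMS (0.32; the other gave -0.64) had the opposite sign. Hypoxia-induced genes had a median of 0.34, with 13 of 19 members higher (camera adjusted p = 0.0714). Among the higher ones was the mitophagy receptor BNIP3L (2.01-fold), and 0 members passed over the list alone. NOTCH1 target genes had a median of -0.22, with 11 of 17 lower (camera adjusted p = 0.55), and DTX1 was the single member past the threshold over the list alone; without MOLT3, P12-ICHIKAWA and PF382 the median was -0.65. For the components of PI3K, AKT and mTOR signalling the median was -0.15 over 39 genes and 0 passed over the list alone. SOCS1, which restrains JAK kinases, differed by -2.97 ± 0.68 and IFIT1, an interferon-induced gene, by 1.98 ± 0.44; each passed over its own list alone and not over all genes, and the 3 other probe sets of SOCS1 ran from -2.34 to 0.24. Among markers of B cells 8 of 10 were lower in resistant lines (median -0.39, camera adjusted p = 0.138), but the median was -0.05 without the same 3 lines. Without them it was -0.38 for cell cycle and 0.96 for hypoxia-induced genes. A fixed term for these 3 lines, all resistant, leaves the class difference to CCRF-CEM and RPMI8402 against the 5 sensitive lines. With that term 8 lists passed in camera at the preset correlation, among them cell cycle (adjusted p = 0.00127) and hypoxia-induced genes (0.000813). NOTCH1 targets (0.0671) and B-cell markers (0.856, direction up) did not pass. With an estimated correlation 0 passed, and the camera adjusted p was 0.339 for cell cycle, hypoxia-induced genes and NOTCH1 targets alike.

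The last comparison asked how the lines differ from one another. Levels of leukaemia oncogenes differed among the lines, and some were shared by several. TLX1, a homeobox gene, read 10.48 in ALL-SIL and was at the floor in the other 9 lines; its relative TLX3 read 8.83 in DND41 and 9.69 in HPB-ALL and at most 6.44 elsewhere. LMO2 read 11.49 in KOPTK1, 10.89 in P12-ICHIKAWA, 9.15 in PF382, 8.42 in MOLT3 and 8.24 in CCRF-CEM, and at most 5.89 elsewhere. LMO1 read 8.43 in RPMI8402, and LYL1 read 9.90 in RPMI8402 and 8.68 in CCRF-CEM. TAL1, a basic helix-loop-helix factor, read 8.91 in RPMI8402, 8.86 in PF382, 7.92 in CCRF-CEM and 7.40 in MOLT3, but 5.36 in P12-ICHIKAWA; of its 2 other detected probe sets, 1 was highest in RPMI8402 (7.91) and 1 in ALL-SIL (7.55).

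The thymocyte-stage genes divided the lines too. CD1B, a lipid-presenting molecule of cortical thymocytes, was at or near the floor in CCRF-CEM (5.17) and RPMI8402 (5.21) and reached 12.40 in CUTLL1, 12.10 in MOLT3 and DND41, and 12.03 in P12-ICHIKAWA. CD34, a progenitor marker, read 11.31 in RPMI8402 against at most 7.01 elsewhere. RAG1, which cuts receptor genes for recombination, ranged from the floor in RPMI8402 and ALL-SIL to 11.38 in HPB-ALL. CDKN2A, a cell cycle inhibitor, read between 5.22 and 6.69 in the 5 resistant lines and 6.23 in ALL-SIL, and between 9.24 and 11.34 in CUTLL1, DND41, HPB-ALL and KOPTK1; on its other detected probe set these 4 read 6.33 to 8.79 and the rest at most 5.84. MTAP, its neighbour, was at the floor in CCRF-CEM, P12-ICHIKAWA, PF382, RPMI8402 and ALL-SIL, but read 8.14 in MOLT3. Of 4 other detected MTAP probe sets 1 was at the floor in the same 5 lines; the others were not, with 6.24, 6.36 and 6.88 in ALL-SIL.

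**Figure D4:**
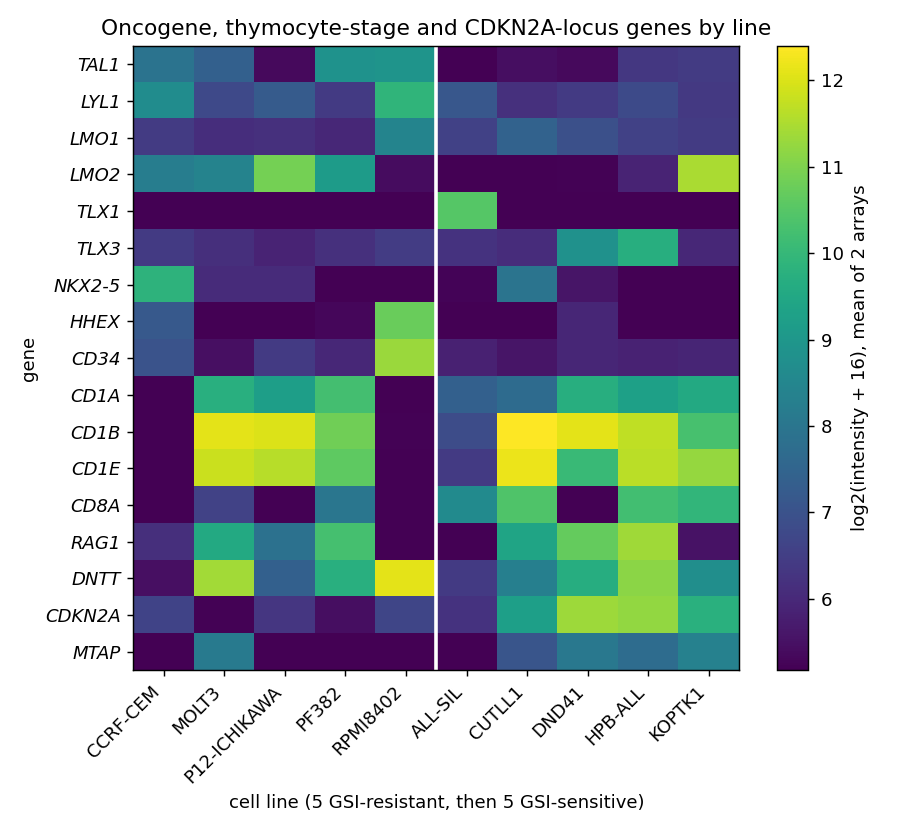
Levels of 17 genes from the oncogene, thymocyte-stage and CDKN2A-locus lists in each of the 10 lines, as log2(intensity + 16), mean of 2 arrays; 5 resistant lines stand left of the white line and 5 sensitive ones right of it. Dark cells are at or near the floor of 5.17.

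Differences between lines were far larger than those between duplicates. In limma's F-test 13521 of 14468 genes (93.5%) differed among the 10 lines. Response class took 19.1% of the variance, lines within a class 75.5% and duplicates 5.44%. Any split of the lines takes some of the variance, and the share of other splits was not computed. The blocks of arrays described above, each within 1 class, may also add to the share of class. The 133 genes that singled out a line by at least 2 log2 units comprised 38 higher and 95 lower ones. This balance depends on the processing: with no filter it was 107 higher and 95 lower, and with pseudocount 64 35 and 31. The filter on the mean level can leave out genes high in 1 line alone, such as TLX1, which was not tested here. RB1, the retinoblastoma tumour suppressor, was at the floor in ALL-SIL and at 10.04 or above in the other 9 lines, but another detected probe set of RB1 read 9.51 in ALL-SIL. SLC2A5, a fructose transporter, read 11.47 in CCRF-CEM against at most 6.31 elsewhere, and HMGB3 5.41 there against at least 9.57. PRDX2, a peroxidase, read 5.23 in DND41 against at least 10.03, where CD38 reached 10.88. SFT2D1 was low in RPMI8402 (5.36 against at least 9.73), and KLHL9 was at the floor in PF382 (at least 8.69 elsewhere). For SLC2A5, SFT2D1 and PRDX2, 1 other detected probe set each did not put the line named beyond the other 9. PCDH9 (11.56 against 7.72) marked HPB-ALL, SHISA2 (11.67 against 9.61) KOPTK1, PLEKHG1 (9.91 against 7.88) CUTLL1, and FARS2 (9.97 against 7.85) MOLT3. No gene singled out P12-ICHIKAWA, and each line rests on 2 cultures.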

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

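All tests in this part on the cluster of 3 lines and on CUTLL1 replicate 1 were chosen after the values had been seen; the count of splits for lists was planned before its result, those for genes and for lists with an estimated correlation after. In 317 groups of 5 line means over 160 genes picked by the naming rule, 23 had an extreme line far from the other 4 relative to the range of the group. Chance alone flags about 1 in 20 groups without ties, so single entries carry little weight. Where the other 4 lines tie at the floor the rule flags the fifth at any distance. This holds for ALDH1A2, ONECUT2, TLX1, HHEX and MTAP, to which that rate does not apply.

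Where 2 values are given, the second is that of the nearest other line of the class. Among sensitive lines, HPB-ALL was high in ALDH1A2 (8.52), ONECUT2 (5.74 against 5.17) and CD8B (8.13). On another detected CD8B probe set CUTLL1 (10.38) read close to HPB-ALL (10.55). ALL-SIL was high in TLX1 (10.48) and low in GATA2 (6.62 against 7.57). On the other detected GATA2 probe set ALL-SIL (6.861) was not the lowest, with CUTLL1 at 6.815 and KOPTK1 at 6.844. KOPTK1 was high in LMO2 (11.49) and GZMA (9.09). DND41 was low in BCL11B (9.69 against 10.88) and high in HHEX (5.96 against 5.17). CUTLL1 was high in NRARP (10.73), a NOTCH target and feedback regulator, in NKX2-5 (7.95) and, near the floor, in KIT (5.543 against 5.215). It was low in CTBP1 (10.19 against 10.97) and CD34 (5.59 against 5.85). Among resistant lines, CCRF-CEM was high in NKX2-5 (9.85) and TNFRSF10B (8.36) and low in NOTCH4 (5.17 against 7.35) and REL (8.32 against 9.19). RPMI8402 was high in CD34 (11.31) and LMO1 (8.43), P12-ICHIKAWA in MIB2 (8.68), PF382 in KIT (6.12) and MOLT3 in MTAP (8.14).

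Of 100 splits of the 10 lines into 5 and 5, 1, the real one, gave 13 genes or more. The highest other, with HPB-ALL in place of MOLT3, gave 9. These splits were run only at the main setting, where the threshold was just crossed, and not at settings where the real count was 0. They also treat the lines as interchangeable, although MOLT3, P12-ICHIKAWA and PF382, all resistant, stand apart as a block. Chance is therefore not excluded for the count of genes. For gene lists 94 of the 100 splits gave at least 1 list and the highest other gave 12, against 1 in the real split, so chance cannot be excluded there. With an estimated correlation 2 of the 100 splits gave at least 1 list and the real one gave 0, so the many calls rest on the preset correlation of 0.01; whether a structure of the samples adds to them was not tested.

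MOLT3, P12-ICHIKAWA and PF382 stand apart on probe sets that lymphoblasts should not use. There ALL-SIL, HPB-ALL and KOPTK1, all sensitive, form the next block (0.41 against 0.47). Over all genes tested MOLT3, P12-ICHIKAWA and PF382 correlate with one another at 0.42. All correlations in this paragraph are taken after subtracting each probe set's mean over the arrays, so values below 0 do not mean opposite levels. Plain correlations between arrays of different lines reach 0.947. A shared response class as the cause stays open: the other resistant lines, CCRF-CEM and RPMI8402, correlated with the 3 lines at a mean of -0.24 and the sensitive lines at -0.26, a difference of 0.0126 (exact permutation p = 0.381, one-sided; the smallest that 21 pairs of lines can give is 0.0476). A difference between array or library batches is a candidate explanation: hybridisation spike-ins, which do not come from the cells, were 0.79 log2 units higher in these 3 lines (exact permutation p = 0.00833, the smallest that 120 trios of lines can give), but only 0.0074 higher in the block of ALL-SIL, HPB-ALL and KOPTK1. The labels give no batch, the spike-in level also depends on scaling, and a biological likeness of the 3 lines stays open and untested.

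CUTLL1 replicate 1 carries labels for both vehicle and inhibitor. If it had received the inhibitor, NOTCH1 targets could be lower than in replicate 2, but their median difference was 0.0202 log2 units, inside the range of the other 9 lines (-0.31 to 0.05). The members went both ways, 10 higher or equal and 7 lower, so the median decides nothing: HES4 (0.93), NOTCH3 (0.77), PTCRA (0.70), DTX1 (0.54) and CCND3 (0.38) lay above every other line, against the inhibitor, and HES1 (-0.57) and HEY1 (-0.74) below every other line, all 7 picked after their values were seen. Another extraction reagent may have left more genes apart: 114 genes differed by over 1 log2 unit between the duplicates, inside the range of 18 to 248 in the other lines. Neither label can be ruled out from these values.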

How the results depend on the processing

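Alternatives using clusters of arrays, and single arrays left out of the comparisons among lines, were chosen after the data had been seen; the others were planned. The count of 13 genes between classes is not stable. It fell to 0 with array medians set equal, pseudocount 64, the 60th percentile filter, probe sets of shared or cross-hybridising type left out, only replicate 1 of each line, and variances moderated without a trend; the cause was not tested. It was 16 with only replicate 2 of each line, and 14 with quantile normalisation and with robust moderation. With no filter it was 4, all lower in resistant lines and none of them among the 13. It was 7 with pseudocount 1, 30 with all probe sets and 7 without MOLT3, P12-ICHIKAWA and PF382 (fewer lines). With clusters as a fixed term it was 9 for 2 clusters and 4 for 3 clusters. Such terms leave CCRF-CEM and RPMI8402 against the 5 sensitive lines with 2 clusters, and against CUTLL1 and DND41 with 3. Taking 20 arrays as independent gave 2873 (1124 higher, 1749 lower), which counts each line as 2 replicates. The line as a random block gave 206 (112 higher, 94 lower). Leaving out each line, or CUTLL1 replicate 1, gave 0 to 61: 61 without RPMI8402 (22 higher, 39 lower), 45 without CCRF-CEM (27 higher, 18 lower), and 4 or fewer without any other line.

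Replicate numbers do not pair lines: deviations of same-numbered arrays correlated above 0.1 in 5 of 45 pairs. The replicate block on top of the random line block gave 178 genes between classes, and among lines the block gave 13482 genes.

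The number of lists was 1 and became 0 with an estimated correlation and with fry's directional test, 2 with no filter and with the 60th percentile filter, 8 without the 3 lines and with 2 clusters, and 10 with 3 clusters; leaving out lines gave 1 to 4. No panel gene passed under any setting run (0 throughout), which says little. In the main run, 1 gene alone at the smallest exact permutation p of 0.00794 has an adjusted p of 0.143 over the 18 panel genes. Genes differing among lines stayed within 1.5 times of 13521, from 13300 to 13678 without single arrays. Genes singling out a line numbered 66 with pseudocount 64 (35 higher, 31 lower) and 202 with no filter (107 higher, 95 lower), against 38 higher and 95 lower in the main run. They numbered 805 at a gap of 1 (286 higher, 519 lower) and 25 at a gap of 3 log2 units (5 higher, 20 lower). Without single arrays they numbered 120 to 152. Of 510 values of named genes and of the cholesterol list under alternatives, 255 stayed on their side of the threshold, 236 lost it, 19 gained it and 0 reversed. ONECUT2 differed by 0.51 with quantile normalisation, 0.57 with pseudocount 1 and 0.42 with only replicate 1, against 2.80. SYNGR1 differed by 0.04 without the shared or cross-hybridising types, against 2.61. Signal near the floor limits the fold of low genes.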

Other observations

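The test on PF382 was chosen, and its settings set, after the genes had been seen.

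Some further members of the fixed lists differed between classes without passing limma's threshold over all genes. PSAT1, a serine synthesis enzyme, read 10.48 ± 0.72 (SD, n = 5) in resistant and 7.40 ± 2.39 (SD, n = 5) in sensitive lines, and the integrin ITGA6 9.21 ± 1.31 against 7.49 ± 1.16; neither passed limma's threshold over all genes (adjusted p = 0.185 and 0.264), and their other detected probe sets gave 1.78 and 1.41. Of the cortical thymocyte list, CD99 differed by -1.13 ± 0.27 (SE) and CD8A by -2.85 ± 0.96, and CD99 alone passed over the list alone. PDK1 and AK4, which are induced in hypoxia, differed by 1.46 ± 0.63 and 1.85 ± 0.80 (SE), also short of the threshold; other probe sets gave 0.12 and 0.63 for PDK1 and 1.20 for AK4.

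MTAP and neighbouring genes at the floor in PF382 were looked at further. KLHL9 was at the floor there and at 8.69 or above elsewhere, and FOCAD was at the floor there and at 6.61 or above elsewhere; both lie near MTAP, were picked after their values were seen, and FOCAD falls outside the naming rule. CAAP1 and PLAA, on the same chromosome, read 9.38 and 8.27 in PF382, and other MTAP probe sets read 5.17 to 6.33 there. Loss of a chromosome segment is a candidate explanation that no test here decides: a permutation test of near pairs among genes at the floor in PF382 (p = 0.007) restates the observation, since its 3 pairs are MTAP, KLHL9 and FOCAD themselves. It passed in only 4 of 9 settings of the level minimum and the window (p from 0.003 to 1), and CCRF-CEM, RPMI8402 and ALL-SIL also passed at the first setting.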
